A study of Danio rerio with 14 samples.

How the data were processed

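Total RNA of 14 pools of 50 zebrafish embryos was labelled with Cy3 (LowInput QuickAmp) and read on single-colour Agilent arrays, per the labels. Exposure to 11-ketotestosterone ran from 96 to 120 hours after fertilisation in a single experiment with 3 controls and 11 concentrations. Per the file headers, the intensity in each scanner file is the background-subtracted and spatially detrended signal of Agilent Feature Extraction 10.7.3.1, with low values replaced by a surrogate and no scaling between arrays. The submitters' processing notes give version 10.1.1.1 instead, and the headers are those of the files used. The deposited series matrix holds log2 values, which the labels do not describe further. Its ranks within each array equal those of the scanner intensity (Spearman's rho 1.0 across spots on each array) and its quantiles are shared between arrays, so it was taken as quantile-normalized log2 intensity, an inference from the values. It served as an alternative only.

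The main values were log2 processed signals, scaled on each array so that the 75th percentile was equal. Spots called outliers by the scanner software were removed, and replicate spots were averaged per probe. The arrays hold 61657 spots of 43603 probes, and 1319 control spots besides. A current gene symbol was given to 37025 probes: 27969 by sequence accession, 3711 by symbol, 1163 by synonym, 1569 by gene identifier, and 2613 kept the name in the file. The other 6578 probes kept their identifier. Names came from gene tables of assembly GRCz12tu, used for names alone, while probe positions are those of the files on danRer7 (Zv9), for which no annotation was at hand. Of 20199 symbols, 10195 have more than 1 probe, and the probe with the highest mean signal stood for the gene. Genes well above background, by the scanner software's own flag, on at least 3 of 14 arrays were kept, which left 24324 genes or unnamed probes, 200 of them with a missing value.

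Groups and slides were taken from the labels and from the position in the file names. The concentration trend was a limma fit (version 3.58.1 in R 4.3.3) of the slope on log10 of the concentration in nM plus 0.05, over all 14 arrays with slide as a term and 11 residual degrees of freedom. The arrays at 500, 1500 and 5000 nM were compared with the 3 controls on slide 2 in limma (4 residual degrees of freedom). The trend from 0.05 to 150 nM was fitted on the 8 arrays of slide 1 (6 residual degrees of freedom). All limma tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Sign between slides was compared for the 100 genes with the smallest p on slide 2, against 100 orders of the slide 1 concentrations, the real one included. The concentration for 50% of the response came from least squares with a slide term over 301 grid values from 0.01 to 10000 nM, with a 95% profile interval. With the slide term in the trend model, 58 genes differed between slides, and 90 without a concentration term.

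Gene lists were tested with camera in limma with a preset correlation of 0.01 and adjusted over 37 lists. The lists held 852 distinct genes, of which 787 were on the arrays. They were androgen-responsive genes reported in zebrafish, steroid receptors, steroid synthesis and inactivation, oestrogen-responsive genes, glucocorticoid-responsive genes, aryl hydrocarbon receptor targets, cytochrome P450 drug metabolism, sulfotransferases and glucuronosyltransferases, bile acid and organic anion transport, thyroid axis, pituitary and gonadotropin axis, gonad differentiation, germ cells, oxidative stress response, heat shock response, endoplasmic reticulum stress, cholesterol synthesis, fatty acid and lipoprotein metabolism, gluconeogenesis and insulin signalling, lens crystallins, photoreceptors, skeletal muscle, exocrine pancreas, liver secreted proteins, intestine, red blood cells, neurons, glia and myelin, cell proliferation, epidermis and ionocytes, cartilage and bone, innate immunity and inflammation, circadian clock, immediate early genes, hair cells and lateral line, kidney, and hypoxia response. Some genes stand in more than 1 list.

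Named genes followed a rule. For the trend they were the 15 that rose and the 10 that fell with the largest fitted change among those past the threshold that have a symbol and move the same way on each slide. For 500 to 5000 nM against control they were the 15 that rose and the 10 that fell with the largest fold past the threshold, with every treated array on the same side of every control. From 0.05 to 150 nM they were the 5 each way with the largest slope past the threshold. Where fewer than 5 passed in a direction, the 5 with the smallest p were named and said not to pass. List members were named as examples or because they passed adjusted over their list alone, and androgen list genes and ar were given whatever their values. The groups, comparisons, lists, this rule and all but 3 of the alternatives were fixed before the data were examined.

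Alternatives were quantile normalization, normexp background correction (offset 50) with either scaling, the authors' series matrix, no filter or a filter on all arrays of the fit, the mean of all probes or every probe on its own, array weights, an intensity trend in the prior variance, saturated probes left out, each array left out in turn, no slide term, slide as a random block, row on the slide, other concentration scales (rank, a saturating scale with 5 nM, and 0.5 or 0.005 nM added), treated arrays alone, a free Hill slope from 0.5 to 4, and an estimated correlation in camera. Leaving out probes with 5 or more CA or TG units, array brightness as a covariate, and leaving out the 3 dimmest arrays were chosen after seeing the data. Where an array was left out, the spread was that of the remaining arrays.

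The fits were tested on simulated data with 200 changed genes, 100 of them by 1 and 100 by 2 log2 units. The trend found 69% and 89% of these, with 14 false among 172 calls. The comparison of 500 to 5000 nM with control found 26% and 81% (5 false of 112), and the trend from 0.05 to 150 nM found 16% and 72% (6 false of 94). A planted list was called and 0 unshifted lists were called in both list tests. The simulated noise was independent between genes, whereas the estimated correlation in the trend was 0.59 for lens crystallins. The simulation therefore does not show how often lists of correlated genes are called falsely. The simulated concentration for 50% response of 10.0 nM was estimated at a median of 9.78 nM, with 95% of intervals holding it. That simulation planted a change of 2 log2 units with a noise SD of 0.25, at this concentration alone. It does not show how the intervals behave for smaller changes or other concentrations, such as dhrs3a (fitted change -0.60, 1.0 nM). Tables were prepared with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures with matplotlib 3.10.9.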

Results

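Expression was measured in whole zebrafish embryos given 11-ketotestosterone (11-KT), an androgen of fish, from 96 to 120 hours after fertilisation. Each of 14 pools of 50 embryos gave 1 single-colour Agilent array. The pools were 3 controls and 1 pool at each of 11 concentrations: 0.05, 0.15, 0.5, 1.5, 5, 15, 50, 150, 500, 1500 and 5000 nM. The concentrations therefore have no replicates, and nothing in the labels separates the 3 controls beyond their pools. A p-value here measures only the spread between pools or around a fitted line. The 8 arrays from 0.05 to 150 nM were on slide 1, in order of concentration by position. The controls and the arrays at 500, 1500 and 5000 nM were on slide 2. The 75th percentile of the intensity ran from 570.2 at 5 nM to 2107 at 0.05 nM. Between 75.6% (0.5 nM) and 92.1% (50 nM) of probes were well above background, and 0 spots were saturated. The median coefficient of variation of replicate spots was 19.2% at 500 nM, and from 8.8% (0.15 nM) to 12.2% (50 nM) on the other arrays. The number of arrays limits the precision. Across all genes, pairs of controls correlated with Pearson's r of 0.992 to 0.994, although genes are not independent replicates, and the median SD between controls was 0.13 (log2). The first principal component of the 14 arrays held 20.6% of the variance and followed array brightness, with an absolute Pearson's r of 0.902 (permutation p = 1e-05, the smallest the permutations can give) and an absolute Spearman's rho of 0.868 (permutation p = 0.00013). Adjusted over the 2 relations examined, these p were 2e-05 and 0.00026, both two-sided. The absolute r was 0.836 without the 2 arrays farthest from the median brightness, 0.945 within slide 1 (8 arrays) and 0.752 within slide 2 (6 arrays).

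The study's title names its aim as finding androgen-responsive genes, and the fit over all 14 arrays asked which genes follow the concentration. Each change is the fitted slope over the 5 log10 units from control to 5000 nM, with slide as a block. The transcript of sult2st3, a sulfotransferase, rose by 2.97 on the log2 scale (SE 0.25, 14 arrays, 7.83-fold, adjusted p = 0.000242) from a control mean of 7.81 ± 0.10 (SD, n = 3). The cytochrome P450 gene cyp2k22 rose by 2.53 (SE 0.36), the hepatic lipase gene lipca by 1.69 (SE 0.20) and the insulin gene insb by 2.29 (SE 0.34), insb with 10 of 14 arrays well above background and a value of 0.61 that did not pass after normexp correction with 75th percentile scaling. The cryptochrome genes cry3b and cry4 rose by 1.42 (SE 0.19) and 0.60 (SE 0.09), and cpt1b, whose product brings fatty acids into mitochondria, rose by 0.78 (SE 0.12). The aquaporin gene aqp8b fell by 1.86 (SE 0.19, adjusted p = 0.0018), and zgc:193593 fell by 2.33 (SE 0.27). The transcription factor genes fosb, fosab and egr4 fell by 1.85 (SE 0.20), 1.68 (SE 0.27) and 1.44 (SE 0.22). The gene lrata, which esterifies retinol, fell by 1.38 (SE 0.18), and dhrs3a, which reduces retinaldehyde, fell by 0.73 (SE 0.12).

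The other named genes that rose were si:dkey-79p17.2 (1.60), si:rp71-1f1.4 (1.58), crtac1a (1.26), si:dkey-23o4.6 (1.24), the prostaglandin D synthase gene ptgdsb.1 (1.16), the cell cycle inhibitor gene cdkn1d (0.93), fam13b (0.87) and prom1b (0.86), and tent5ab fell by 1.22. In limma, 28 of 24324 genes or unnamed probes passed a Benjamini-Hochberg adjusted p of 0.05, of which 19 rose and 9 fell, and 23 of them have a symbol. An unadjusted p under 0.05 was found for 1718, where 1216 would be expected by chance. The count was 64 (47 rose, 17 fell) with normexp and quantile normalization, 418 (252 and 166) with array weights, 60 (47 and 13) with the filter on all arrays, 59 (45 and 14) with an intensity trend in the prior variance and 51 (40 and 11) with every probe on its own. It was 17 without a filter (11 and 6) and 17 on a saturating scale (10 and 7). All 28 moved the same way on both slides, which a fit to both slides favours. Within slide 2 and within slide 1, sult2st3 differed by 2.62 and 2.13, cyp2k22 by 2.37 and 1.63, lipca by 1.65 and 0.82, insb by 1.76 and 2.25, aqp8b by -1.53 and -1.64, zgc:193593 by -1.93 and -2.04, and fosb by -1.62 and -1.29. A second probe gave 1.34 for cyp2k22 and -0.59 for fosb, and 1 of 5 other probes of fam13b went the opposite way (-0.08). On danRer7 (Zv9) the sult2st3 probe lies on chromosome 16 from 47820296 to 47820355, the cyp2k22 probe on chromosome 3 from 8814276 to 8814335, the lipca probe on chromosome 7 from 31742862 to 31742921 and the insb probe on chromosome 14 from 29583414 to 29583473. The aqp8b probe lies on chromosome 3 from 18301591 to 18301650 and the fosb probe on chromosome 18 from 35113503 to 35113562, and no annotation of that build was at hand to say which exon each meets. Without single arrays the count of 28 became 8 (without control 1), 18 (without control 2, control 3 or 0.5 nM), 53 (5 nM), 12 (50 or 500 nM), 10 (150 nM), 7 (1500 nM) and 11 (5000 nM), and only sult2st3, lipca, si:dkey-23o4.6, aqp8b, fosb and zgc:193593, 6 of the 23 named genes, passed without any 1 array. On the treated arrays alone, 2 genes passed, and none of the 23 was among them, with values such as -2.73 for zgc:193593 (adjusted p = 0.0853) and -2.21 for aqp8b (0.0685), but 0.63 for cry3b and 0.59 for crtac1a. The value of sult2st3 was at least 2.36 in all 36 alternatives, and its highest adjusted p was 0.0890, on the treated arrays alone. With normexp and 75th percentile scaling the calls of insb, prom1b, crtac1a, dhrs3a, tent5ab, cdkn1d and si:rp71-1f1.4 (0.76) ended, and without a filter those of prom1b, crtac1a, ptgdsb.1, dhrs3a, tent5ab, si:dkey-79p17.2 and fosab. With the mean of all probes of a gene those of cry3b, cry4 and fosab ended, and without slide in the model, or with slide as a random block, those of prom1b, crtac1a, ptgdsb.1, dhrs3a, cry3b, si:dkey-23o4.6 and si:dkey-79p17.2. On a saturating scale those of lrata, dhrs3a, prom1b, crtac1a, ptgdsb.1, cry3b, cry4 and cpt1b ended, and with row on the slide as a covariate those of prom1b, ptgdsb.1 and tent5ab. That of prom1b also ended with the log10 of dose plus 0.5. Of the alternatives chosen after seeing the data, array brightness as a covariate ended that of tent5ab, and leaving out the 3 dimmest arrays those of prom1b, egr4 and fosab.

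**Figure D1:**
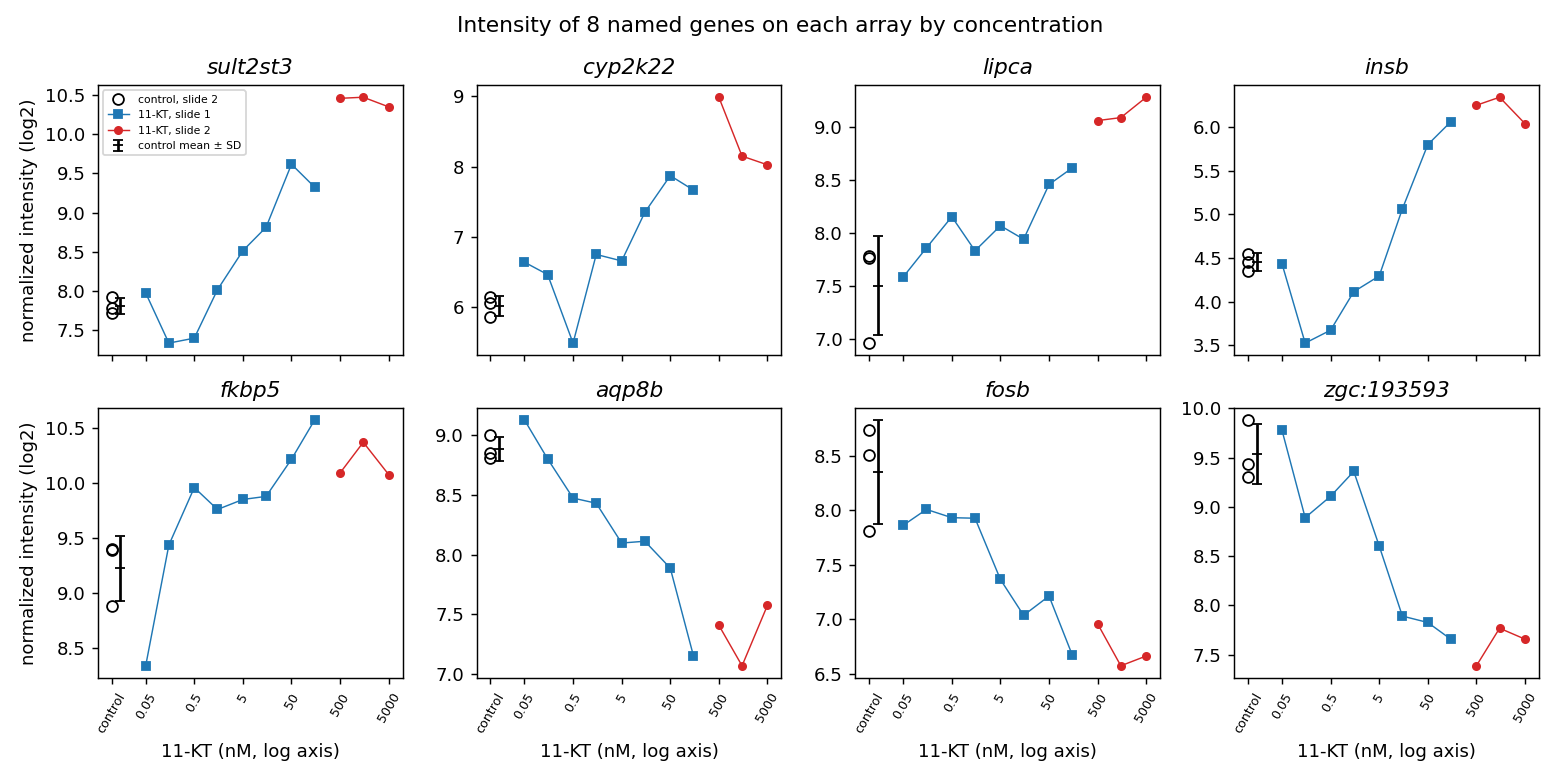
Normalized log2 intensity of 8 genes (vertical axes) on each array against the 11-KT concentration in nM (log axis), with slide 1 in blue squares, slide 2 in red circles and the 3 controls as open circles beside their mean and SD. For sult2st3 the controls average 7.81 and the 3 highest concentrations 10.43, and for aqp8b the controls average 8.88 and the 3 highest concentrations 7.35.

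Gene lists were tested on the same 14 arrays, and 11 of 37 passed in camera. All 7 genes of the list of androgen-responsive genes reported in zebrafish were measured: 3 rose, 0 fell and 4 did not pass over all genes, and adjusted over the list alone 5 rose and 1 fell. Their median change was 1.35 (0.95 on slide 2, 0.82 on slide 1), with adjusted p = 6e-11 and adjusted p = 0.00113 with an estimated correlation. Over all genes, fkbp5, which encodes a chaperone of steroid receptors, did not pass (1.35, adjusted p = 0.125), and neither did the anion transporter gene slco1f4 (0.63, adjusted p = 0.0779), whose other probes gave 2.94 and -0.14. These 2 probes were well above background on only 6 and 3 of 14 arrays. The values of sult1st1 and cyp2k16 were -0.34 (SE 0.15) and 0.05 (SE 0.17), and the androgen receptor gene ar did not pass (0.21, SE 0.12, adjusted p = 0.807). The list comes from reports that may rest on these same samples, so its count is not independent evidence. Androgen-responsive genes were the only list past the threshold with an estimated correlation.

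Of 21 genes of the exocrine pancreas list, 0 passed over all genes, and adjusted over the list alone 8 rose, among them cel.1 (0.82, SE 0.16), the amylase gene amy2a (0.62, SE 0.17) and the carboxypeptidase gene cpa1 (0.71, SE 0.24). The list's median was 0.39 (0.34 on slide 2, 0.07 on slide 1), with adjusted p = 6e-11 and adjusted p = 0.269 with an estimated correlation. Of 30 genes for liver secreted proteins, 0 passed over all genes and, adjusted over the list alone, 6 rose, with the hemopexin gene hpxa at 1.66 (SE 0.35), ahsg2 at 0.86 (SE 0.18) and the ceruloplasmin gene cp at 0.52 (SE 0.12). That median was 0.14 (0.18 on slide 2, 0.0063 on slide 1), with adjusted p = 0.000448 and adjusted p = 0.58 with an estimated correlation.

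Of 32 immediate early genes, which cells induce within minutes of a stimulus, 3 fell over all genes (fosb, fosab and egr4), and adjusted over the list alone 7 fell and 1 rose. Among these, npas4a fell by 1.304 (SE 0.31) and ier2b fell by 0.82 (SE 0.25), while nr4a1 rose by 0.67 (SE 0.15). The median was -0.11 (-0.10 on slide 2, -0.13 on slide 1), with adjusted p = 0.00134 and adjusted p = 0.359 with an estimated correlation. Of 37 circadian clock genes, 0 passed over all genes, and adjusted over the list alone 6 rose, such as nfil3-6 (0.94, SE 0.22), rorca (0.83, SE 0.22) and cry3a (0.68, SE 0.16), and 2 fell (ciartb fell by 0.54, dbpa fell by 0.44). The clock median was 0.13 (0.05 on slide 2, 0.18 on slide 1), with adjusted p = 0.0203 and adjusted p = 0.325 with an estimated correlation. The clock list no longer passed without the array at 0.05 nM (adjusted p = 0.0707) or at 150 nM (0.0693), or with the mean of all probes of a gene (0.105).

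Genes that respond to glucocorticoids passed as a list: 0 of 18 passed over all genes, and adjusted over the list alone 6 rose, including hsd11b2, which inactivates cortisol (0.79, SE 0.16), the tyrosine aminotransferase gene tat (1.04, SE 0.35) and klf9 (0.61, SE 0.19). The glucocorticoid median was 0.12 (0.20 on slide 2, 0.08 on slide 1), with adjusted p = 0.00187 and adjusted p = 0.359 with an estimated correlation, and fkbp5 stands in this list and in that of androgen-responsive genes. Of 19 genes of gluconeogenesis and insulin signalling, 1 rose over all genes (insb), and adjusted over the list alone 2 rose, insb and igfbp1a (0.997, SE 0.21), which encodes a binding protein of insulin-like growth factors. That median was 0.09 (0.07 on slide 2, 0.09 on slide 1), with adjusted p = 0.00155 and adjusted p = 0.0529 with an estimated correlation.

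Of 30 lens crystallins and lens genes, 28 had a positive slope and 0 passed, over all genes or adjusted over the list alone, with crygm7 at 1.67 (SE 0.61) and cryaa at 1.17 (SE 0.62). The lens median was 0.62 (0.17 on slide 2, 1.36 on slide 1), with adjusted p = 2.09e-05 and adjusted p = 0.584 with an estimated correlation. Of 32 genes of photoreceptors, 0 passed over all genes and, adjusted over the list alone, 5 rose, such as the cone arrestin genes arr3b (0.95, SE 0.23) and arr3a (0.87, SE 0.22). The photoreceptor median was 0.20 (0.0046 on slide 2, 0.47 on slide 1), with adjusted p = 0.00528 and adjusted p = 0.626 with an estimated correlation. Of 27 genes of neurons, 24 had a positive slope and 0 passed either way (gad1b 0.43, SE 0.19), with a median of 0.11 (0.07 on slide 2, 0.15 on slide 1), adjusted p = 0.00954 and adjusted p = 0.584 with an estimated correlation. Of 16 genes of the heat shock response, 0 passed over all genes and, adjusted over the list alone, 1 fell: serpinh1b, a chaperone of collagen, fell by 1.22 (SE 0.22). The heat shock median was -0.07 (-0.12 on slide 2, -0.12 on slide 1), with adjusted p = 0.0107 and adjusted p = 0.325 with an estimated correlation. Photoreceptors no longer passed without control 2 (adjusted p = 0.139) or 0.15 nM (0.0596), neurons without 0.05 nM (0.0589) or 5000 nM (0.0625), and heat shock genes without 150 nM (0.0700) or 5000 nM (0.0672). Without the 3 dimmest arrays, an alternative chosen after seeing the data, these adjusted p were 0.225, 0.0739 and 0.103.

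**Figure D2:**
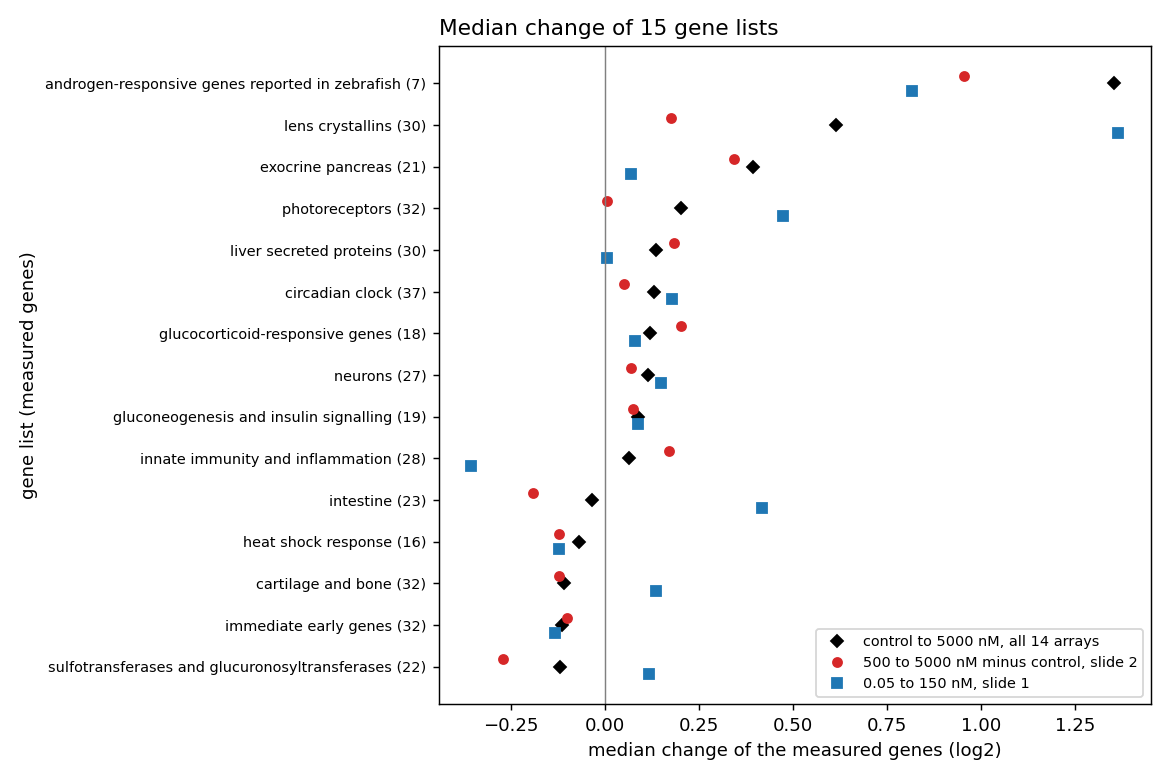
Median log2 change (horizontal axis) of the measured genes of each of the 15 lists that passed in the trend or in the comparison of 500 to 5000 nM with control (vertical axis, with the number measured). Black diamonds are the trend over 14 arrays, red circles slide 2 and blue squares slide 1; the intestine list lies at -0.19 on slide 2 and at 0.42 on slide 1.

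The arrays at 500, 1500 and 5000 nM were set against the 3 controls of their slide, as 1 arm of high concentration. The transcript of sult2st3 rose by 2.62 (SE 0.10, 6.14-fold, adjusted p = 0.00103 in limma), from 7.81 ± 0.10 (SD, n = 3 controls) to 10.43 ± 0.07 (SD, n = 3). The transcript of insb rose by 1.76 (SE 0.11, 3.38-fold, adjusted p = 0.0217 in limma), from 4.45 ± 0.10 (SD, n = 3 controls, 2 of them well above background) to 6.21 ± 0.16 (SD, n = 3). For both genes the 3 treated arrays lay above the 3 controls. No other gene passed, and the values nearest the threshold (adjusted p = 0.0519) included zgc:193593 at -1.93 (SE 0.18), aqp8b at -1.53 (SE 0.15), klhl38b at 1.39 (SE 0.11) and ppp1r27b at 1.36 (SE 0.12). LOC795145, with 0 of 3 controls well above background, had no stable value. Its value was 1.66 in this fit (adjusted p = 0.0519 in limma), or 3.07-fold with the controls raised to the lowest signal called above background. After normexp correction with 75th percentile scaling it was -0.04. A second probe gave -0.33 but was well above background on only 1 of 14 arrays. The values of tent5ab (-1.06), gig2i (-0.78) and ace (-1.0), which encodes angiotensin-converting enzyme, did not pass either. In limma, 2 of 24324 rose and 0 fell, and 14 had an adjusted p between 0.05 and 0.06. An unadjusted p under 0.05 was found for 3473, where 1216 would be expected by chance. An exact permutation test of 3 arrays against 3 has 10 splits and cannot reach 0.05, so the calls rest on the spread pooled across genes. The split of calls was 7 rising and 3 falling with quantile normalization, 150 and 77 with normexp and quantile normalization, 79 and 32 with normexp and 75th percentile scaling (without insb), and 9 and 3 in the authors' series matrix. It was 100 and 45 with the filter on all arrays and 212 and 104 with an intensity trend in the prior variance. The value of insb was 0.45, and did not pass, with normexp and 75th percentile scaling, and 0.56 with normexp and quantile normalization. The call of insb ended without each of the 6 arrays in turn (1.69 to 1.84), and the count was 1 without control 1, control 3, 1500 nM or 5000 nM, and 4 without 500 nM.

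In this comparison 9 lists passed in camera, and 0 passed with an estimated correlation. Lists outside the 9 passed without single arrays: lens crystallins (adjusted p = 3.25e-06) and photoreceptors (0.0388) upward without control 3, and kidney downward without 5000 nM (0.00994). Kidney also passed without a filter (0.0315) and with the mean of probes (0.0286). Others that passed in some alternatives were bile acid transport, cell proliferation and endoplasmic reticulum stress downward, and gluconeogenesis and the pituitary axis upward. The exocrine pancreas list had a median of 0.34 (0 of 21 over all genes and 5 rising adjusted over the list alone, cpa1 by 0.78, SE 0.10), adjusted p = 1.39e-06 and adjusted p = 0.563 with an estimated correlation. Androgen-responsive genes had a median of 0.95, with 1 of 7 rising over all genes and 5 adjusted over the list alone, adjusted p = 4.69e-06 and adjusted p = 0.224 with an estimated correlation. The estimated correlation of that list was -0.012, under the preset 0.01, yet its unadjusted camera p went from 2.54e-07 to 0.00605. A higher correlation between its genes therefore did not end this call, and the 2 camera settings differ in more than the correlation. Liver secreted proteins had a median of 0.18, with 0 of 30 over all genes and 7 rising adjusted over the list alone (hpxa by 1.78, SE 0.27, and ahsg2 by 0.84, SE 0.09), adjusted p = 0.000625 and adjusted p = 0.563 with an estimated correlation. Glucocorticoid-responsive genes had a median of 0.20, with 0 of 18 over all genes and 3 rising adjusted over the list alone (tat by 1.43, SE 0.13), adjusted p = 0.0221 and adjusted p = 0.563 with an estimated correlation. Immediate early genes had a median of -0.10, with 0 of 32 over all genes and 8 falling adjusted over the list alone (fosl2 fell by 0.65, SE 0.18), adjusted p = 0.0237 and adjusted p = 0.563 with an estimated correlation. These genes no longer passed without control 3 (adjusted p = 0.0868) or 5000 nM (0.0838), or without probes that hold CA or TG repeats (0.0620), an alternative chosen after seeing the data.

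Genes of the intestine had a median of -0.19 on slide 2, with 0 of 23 past the threshold over all genes and 3 falling adjusted over the list alone. Of these the alkaline phosphatase gene alpi.2 fell by 1.16 (SE 0.16), anpepb.1 fell by 0.71 (SE 0.15) and the apolipoprotein gene apoa4a fell by 0.64 (SE 0.14). The list's adjusted p was 0.000625, and adjusted p = 0.563 with an estimated correlation, while its median from 0.05 to 150 nM was 0.42. Sulfotransferases and glucuronosyltransferases had a median of -0.27 (0.12 on slide 1), with 1 of 22 rising over all genes (sult2st3). Adjusted over the list alone, 2 rose and 6 fell, among them ugt5d1, which fell by 0.66 (SE 0.11), and ugt2b1, which fell by 0.76 (SE 0.19), with adjusted p = 0.0233 and adjusted p = 0.563 with an estimated correlation. Cartilage and bone genes had a median of -0.12 (0.13 on slide 1), with 0 of 32 over all genes, and adjusted over the list alone 1 rose (spp1 by 0.65, SE 0.13) and 2 fell (matn3a fell by 1.39, SE 0.29, entpd5a fell by 0.56, SE 0.13), adjusted p = 0.004 and adjusted p = 0.563 with an estimated correlation. Genes of innate immunity and inflammation had a median of 0.17 (-0.35 on slide 1), with 0 of 28 passing either way (il34 0.38, SE 0.09), adjusted p = 0.0423 and adjusted p = 0.563 with an estimated correlation. The sulfotransferase list no longer passed without control 1 (adjusted p = 0.145) or 1500 nM (0.0562), and innate immunity no longer passed without control 1 (0.104), control 3 (0.0855), 500 nM (0.0676) or 1500 nM (0.134), or with normexp and quantile normalization (0.102). Glucocorticoid-responsive genes no longer passed with the mean of all probes of a gene (0.136).

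From 0.05 to 150 nM, on the 8 arrays of slide 1 and without controls, 0 genes passed in limma, and the smallest adjusted p was 0.132. An unadjusted p under 0.05 was found for 2725, where 1216 would be expected by chance. The genes with the smallest p, given as fitted change from 0.05 to 150 nM, were pkd2l1 (1.85, SE 0.23, with 7 of 14 arrays well above background), LOC100334711 (1.397, SE 0.16), the neutral amino acid transporter gene slc6a19a.1 (1.33, SE 0.23), slc22a7b.1 (1.19, SE 0.18) and reln (1.08, SE 0.19). In the other direction they were gxylt2 (-2.73, SE 0.35), ano10b (-2.55, SE 0.35), aqp8b (-1.64, SE 0.21), serpinh1b (-1.46, SE 0.16) and spire2 (-1.27, SE 0.16). The count was 25 (4 rising, 21 falling) with normexp and quantile normalization, 31 (2 and 29) with the filter on all arrays and 34 (4 and 30) with an intensity trend in the prior variance. In all 3 of these LOC100334711, slc22a7b.1, gxylt2, ano10b, aqp8b and serpinh1b passed. The probes of gxylt2 and ano10b hold runs of CA, and a second probe of reln had an opposite slope over the 14 arrays (-0.45 against 0.51). As lists, lens crystallins (median 1.36, adjusted p = 6.85e-10, adjusted p = 0.605 with an estimated correlation), photoreceptors (0.47, 7.16e-08 and 0.494), intestine (0.42, 0.000568 and 0.605), androgen-responsive genes (0.82, 0.00557 and 0.368), gluconeogenesis and insulin signalling (0.09, 0.0322 and 0.368), circadian clock (0.18, 0.0322 and 0.368) and neurons (0.15, 0.0289 and 0.722) passed upward in camera. Skeletal muscle (median -0.26, adjusted p = 0.0322, adjusted p = 0.722 with an estimated correlation) and innate immunity (-0.35, 0.0322 and 0.722) passed downward. Position on the slide runs with concentration here, and the fit cannot separate them.

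Slides 1 and 2 share no array, so the direction of genes was compared between them. Of the 100 genes with the smallest p between 500 to 5000 nM and control, 51 had a slope of the same sign from 0.05 to 150 nM. The 95% exact binomial interval was 40.8% to 61.1%, but it treats genes as independent and is too narrow. In 48 of 100 permutations of the slide 1 concentrations the number of the same sign was as high (15 to 84 over the permutations). Across all genes the changes on both slides correlated with Pearson's r of -0.17 and Spearman's rho of -0.16, and genes are not independent replicates. The number was 63 without control 3 and 38 without the array at 5000 nM. The genes tat (1.43 on slide 2, -0.57 on slide 1) and ppp1r27b (1.36 and -0.57) had opposite signs on the slides.

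A concentration for a response of 50% was fitted for the 23 named trend genes, with the response of each gene left free in size. The median over the 23 was 12.6 nM, and 6.31 nM without the array at 5 nM to 18.2 nM without that at 15 nM when 1 array was left out. It takes in the point estimates of 9 genes for which only an upper bound can be given, and its range does not carry their uncertainty. For sult2st3 it was 7.94 nM (95% profile interval 2.29 to 28.8), for insb 12.6 nM (3.98 to 38.0), for cyp2k22 12.6 nM (1.32 to 109.6) and for fam13b 69.2 nM (15.1 to 199.5). The insb value rests in part on signal near background, with only 10 of 14 arrays well above it. Of genes that fell, it was 6.31 nM for zgc:193593 (1.58 to 25.1), 5.50 nM for egr4 (1.15 to 31.6), 9.12 nM for fosb (0.832 to 239.9), 13.8 nM for aqp8b (0.182 to 105) and 28.8 nM for tent5ab (5.75 to 145). The lowest values with a bounded interval were 0.724 nM for cdkn1d (0.12 to 4.79) and 1.0 nM for dhrs3a (0.209 to 5.50). For 9 of the 23, including lipca (upper bound 501 nM), cry3b (380.2 nM) and lrata (1096 nM), the interval ran under the tested range, so only an upper bound can be given. The controls sit on slide 2 alone, so for every gene the level at low concentration rests on the fitted difference between slides.

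**Figure D3:**
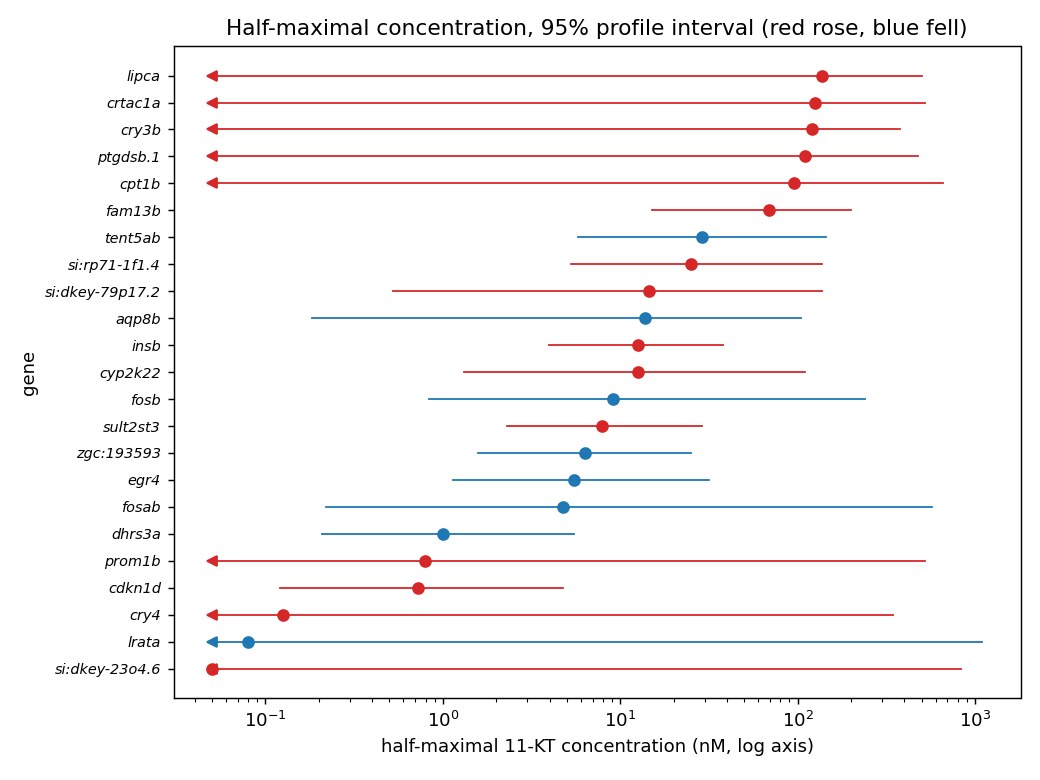
Concentration of 11-KT for 50% of the response (nM, log axis) of the 23 named trend genes (vertical axis), with 95% profile intervals; red rose, blue fell, and an arrow marks an interval that runs under the tested range. The sult2st3 estimate is 7.94 nM, and 14 of the 23 intervals lie within the range.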

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

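The alternatives with CA or TG repeat probes left out, with array brightness as a covariate and without the 3 dimmest arrays were chosen after seeing the data. Over all alternatives, 955 values of named genes kept their direction and their side of the threshold, 205 lost the threshold, 72 passed it newly and 1 reversed: LOC795145 between 500 to 5000 nM and control went to -0.0392 with normexp and 75th percentile scaling. The trend count of 28 became 64 with normexp and quantile normalization, 17 without a filter (26777 tested), 60 with probes well above background on all arrays (19617 tested), 51 with every probe on its own, 418 with array weights, 59 with an intensity trend in the prior variance, 17 on a saturating scale, 2 on treated arrays alone (fewer arrays, and no controls) and 43 without the 3 dimmest arrays. It ran from 7 to 53 when 1 array was left out, and from 19 to 39 otherwise. All 28 were among the 418, the 64, the 59 and the 51. Of the 23 named trend genes, those kept were 8, 14 and 12 without controls 1, 2 and 3, and without 0.05 to 5000 nM in turn 16, 20, 16, 20, 23, 17, 11, 9, 10, 7 and 11. The calls of cyp2k22 (2.27 to 2.84 over the arrays left out) and insb (2.11 to 2.59) ended without control 1, control 3, 150 nM or 1500 nM, and that of insb also without 500 nM. Between 500 to 5000 nM and control, the count of 2 became 10 with quantile normalization, 227 with normexp and quantile normalization, 111 with normexp and 75th percentile scaling, 12 in the authors' series matrix, 145 with the filter on all arrays, 7 with the mean of probes, 23 with every probe, 25 with array weights, 316 with an intensity trend in the prior variance and 35 with row as a covariate. Leaving out 1 array gave 1 to 4. The sult2st3 call held in all 19 alternatives run for it there (2.26 to 2.68). From 0.05 to 150 nM, the count of 0 became 25 with normexp and quantile normalization, 31 with the filter on all arrays and 34 with an intensity trend in the prior variance, and stayed 0 in the others, including all arrays left out (0 to 0). Of the 100 genes compared between slides, 38 to 63 had the same sign when 1 array was left out. The list counts of 11 and 9 became 1 and 0 with an estimated correlation, and ran from 9 to 13 and from 7 to 12 when 1 array was left out. The median concentration for 50% response ran from 6.03 to 18.2 nM over all alternatives, 6.31 to 18.2 nM when 1 array was left out. Numbers tested and arrays used are given in brackets as differences between fits, not as tested causes. The cause of each of these changes was not tested. With 0 saturated spots, leaving out saturated probes changed nothing and tests nothing. Signal over background limits insb (10 of 14 arrays well above background), pkd2l1 (7 of 14) and LOC795145 (6 of 14): with normexp and 75th percentile scaling the trend of insb was 0.61 and the value of pkd2l1 from 0.05 to 150 nM was 0.31.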

Other observations

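The tests of the partner probes of CA-repeat probes, of array position for immediate early genes and of a response already present from 0.05 to 150 nM were chosen after the result was seen, as were the genes fbxo32 and trim63a. Of the other lists over the 14 arrays, none passed in camera, although members of some passed adjusted over their list alone. In alternatives, skeletal muscle passed downward with quantile normalization (adjusted p = 0.0354), normexp and quantile normalization (0.0174), the authors' series matrix (0.0347), a saturating scale (0.0225), and without 0.05 nM (0.0298) or 5000 nM (0.0431). Epidermis and ionocytes passed upward without 0.15, 0.5, 5, 50 or 500 nM, with array brightness as a covariate (0.0277) and without the 3 dimmest arrays (0.00251). Sulfotransferases and glucuronosyltransferases passed downward without control 2, 0.15, 0.5, 15 or 5000 nM, without slide in the model (0.0229) and without the 3 dimmest arrays (0.0265). Intestine and cartilage and bone passed downward without the 3 dimmest arrays (0.0341 for both), and, upward, fatty acid metabolism without control 1 (0.0407) and germ cells without 5000 nM (0.0431). Drug-metabolising cytochrome P450 genes had 1 rising over all genes of 23 (cyp2k22) and, adjusted over the list alone, 2 rising and 3 falling: cyp2k6 rose by 1.07 (SE 0.29), and cyp2aa9, cyp2aa8 and cyp2aa4 fell by 0.95, 1.06 and 0.59. Their median was -0.0069, opposite to their mean of 0.04 and to their test (adjusted p = 0.641). Of 22 genes of endoplasmic reticulum stress (median -0.12, adjusted p = 0.151), 0 passed over all genes, and adjusted over the list alone manf, creld2 and hsp90b1 fell by 0.45, 0.65 and 0.44 while chac1 rose by 0.63. Of 22 genes of the hypoxia response (median 0.07, adjusted p = 0.151), 0 passed over all genes and adjusted over the list alone 4 rose, including igfbp1a and pfkfb4b (0.60), and 2 fell (p4ha1b fell by 0.53, egln3 fell by 0.43). Of 25 genes of fatty acid and lipoprotein metabolism (median 0.07, adjusted p = 0.151), 1 rose over all genes (lipca), and adjusted over the list alone 3 rose, with the pyruvate dehydrogenase kinase genes pdk2a (0.54) and pdk2b (0.63), and 1 fell (apoa4a fell by 0.65). Of 24 genes of cholesterol synthesis, 0 passed over all genes and, adjusted over the list alone, mvda fell by 0.70, while the median (0.05) and mean (0.0028) were opposite to the test (adjusted p = 0.907). Sulfotransferases and glucuronosyltransferases had a trend median of -0.12 (adjusted p = 0.0727), with 1 of 22 rising over all genes and 1 rising and 2 falling adjusted over the list alone.

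Lists of the endocrine axes did not pass in the trend. The median was 0.10 for 7 steroid receptors (adjusted p = 0.427), -0.11 for 21 genes of steroid synthesis and inactivation (0.748; 1 rose adjusted over the list alone, hsd11b2), -0.03 for 9 oestrogen-responsive genes (0.696), 0.04 for 14 genes of the thyroid axis (0.295), 0.25 for 15 of the pituitary and gonadotropin axis (0.16), -0.11 for 14 of gonad differentiation (0.583) and 0.18 for 12 germ cell genes (0.125). It was 0.05 for 8 aryl hydrocarbon receptor targets (adjusted p = 0.641), -0.07 for 17 genes of bile acid and organic anion transport (0.768; 1 rose adjusted over the list alone, slco1f4) and 0.05 for 18 of the oxidative stress response (0.809). Among tissue lists it was -0.09 for 36 skeletal muscle genes (0.229), -0.03 for 23 intestine genes (0.373; 1 fell adjusted over the list alone, apoa4a), 0.09 for 15 of glia and myelin (0.545), -0.04 for 26 of cell proliferation (0.234), 0.10 for 34 of epidermis and ionocytes (0.0884), -0.11 for 32 of cartilage and bone (0.104), 0.06 for 28 of innate immunity (0.816), -0.04 for 21 of hair cells and lateral line (0.907) and -0.07 for 22 of the kidney (0.696). The 22 genes of red blood cells had a median of 0.03, opposite to their mean of -0.01 and to their test (adjusted p = 0.907). Between 500 to 5000 nM and control, the median of steroid synthesis (-0.06) was opposite to its mean (0.07) and test (adjusted p = 0.785), and that of oestrogen-responsive genes (-0.07) to its mean (0.01) and test (0.77). In that comparison the genes fbxo32 and trim63a, which encode ubiquitin ligases of muscle, had values of 1.496 (SE 0.19, adjusted p = 0.0801) and 0.96 (SE 0.10, adjusted p = 0.0554), higher in 3 of 3 treated arrays than in the 3 controls for each.

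From 0.05 to 150 nM, 100 probes with 5 or more CA units in a row had a median change of -1.22, while probes with TG runs went the other way (median 0.92 for 110 probes with 5 to 7 units, 1.13 for 53 with 8 or more). Such CA-repeat probes stood for 59 genes, 25 of them among the 100 genes with the smallest p in limma. They read 24 of the 34 genes with a value under -1.8 and an unadjusted p under 0.002, gxylt2 and ano10b included. These 2 cut-offs were not fixed beforehand. Probes of the same genes without a repeat, at hand for 64 of them, had a median change of 0.000745, against -0.96 for those 64 repeat probes. The change was thus particular to the repeat probes. That is what cross-hybridisation to the repeat would give, but other effects on repeat probes were not tested. Only 7.81% of these repeat probes had partners that fell by at least 0.5 times as much, which argues against a change in the transcripts of their genes. Probes matched on mean signal had a median of 0.0289, which argues against probe brightness. On slide 2, where the treated arrays come first by position, the repeat probes were higher at 500 to 5000 nM than in the controls (median 0.31, partners -0.02), opposite to a fall with concentration, and what made the signal differ along slide 1 stays open.

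The fall of 7 immediate early genes with concentration was weighed against differences between arrays. With array brightness as a covariate 96.6% of their median change remained, and with row on the slide 99.9%. Neither value tests its explanation, because the layout left both covariates almost unrelated to concentration. On slide 1 the later row held the higher concentrations, but on slide 2 it held controls alone. Brightness went up and down along the concentrations. Adding either covariate could therefore hardly shrink the fitted change, whatever these genes did. On slide 2 the treated arrays come before the controls by position. All 7 were lower in them (fosb -1.62, btg2 -0.62), but the fit that chose the 7 holds slide 2, so this tests nothing. The 5 members of the list chosen for a fall along slide 1 alone had a median of -1.20 there (quartiles -1.52 and -0.28). Of these, 4 were lower in the treated arrays and junba was higher (0.29). The upper quartile below 0 argues against array position, and against row, for these members, apart from junba. A fall with the later row along slide 1 would leave the treated arrays of slide 2 higher than the controls. The order in which pools were handled is not in the labels, and a series from control to 5000 nM cannot be told apart from concentration, with 8 of 8 arrays of slide 1 in order of concentration. An effect of 11-KT on these genes stays a candidate explanation beside such a series. The fits with brightness or row did not test those 2 explanations, which only the layout and, for row, the 5 members speak against.

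Of the 100 genes with the smallest p between 500 to 5000 nM and control, all but 51 had a slope of the opposite sign on slide 1. For 99 genes chosen without control 1, which shares its row with the treated arrays, that control lay at a median of 0.0199 of the way from the other controls to the treated arrays (quartiles -0.23 and 0.38), which argues against the row. For 98 genes chosen without the array at 5000 nM, the dimmest of its slide, that array lay at 0.791 of the way (quartiles 0.53 and 0.96), which argues against brightness. Whether a response was already present from 0.05 to 150 nM stays open, since 48 of 100 permutations gave as high a share. A response that starts above 150 nM was not tested.

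Among 100 orders of the concentrations within slides, the real one included, 1 gave as many as the 28 trend genes, and the highest other gave 1, so chance is excluded at the 5% level for that count. Of the 10 splits of the 6 arrays of slide 2, 1, the real one, gave as many as 2 genes and the highest other gave 0, and 10 splits are too few for a share under 0.05. For the trend from 0.05 to 150 nM, 100 of 100 orders gave at least the real count of 0, and the highest other gave 4. A real count of 0 fixes that outcome, so it says nothing about chance.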
